A study of Xenopus tropicalis with 2 samples.

How the data were processed

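The data are 2 sequencing libraries from whole *Xenopus tropicalis* embryos at stage 10.5 (early gastrula), 1 library per group. One library came from chromatin precipitated with a rabbit polyclonal antibody against Smad2/3, the receptor-activated SMADs of Nodal and activin signalling, and the other from Input DNA with no antibody. Per the labels' protocols, nuclei were sonicated, libraries were amplified with 17 PCR cycles and size-selected on a gel, and sequencing was done on a Genome Analyzer II.

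The deposited alignment files hold 1 line for each read of 32 bases, with the number of matches at each mismatch count up to 2 and, where few places matched, their positions. The scaffold names in those files are those of the xenTro2 assembly, and a separate contaminant sequence set also appears among the matches. The layout is that of ELAND extended output, and the aligner's version and settings are not given in the sources used here. The peak list was made with MACS 1.4, per the submitters' processing notes. Its score is the value the authors deposited for each peak, which MACS 1.4 writes as −10 times log10 of the p-value. The control library and threshold used for peak calling are not given in the sources used here. The score was used only to rank and divide peaks within the list.

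No genome sequence or gene annotation of xenTro2 was used here. Peaks are therefore named by scaffold, start and end in xenTro2 coordinates, counted from 1, and are not assigned to genes. The planned comparisons of peaks with transcription starts and with gene lists were not analysed here, and no gene is named as a target. The rule fixed for named items became the 20 peaks with the highest deposited scores.

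Reads were counted by the position of their 5′ end. A read was called uniquely placed when it had 1 match in its best mismatch class. For each peak, uniquely placed reads at distinct positions and strands were counted in both libraries and compared by a two-sided exact binomial test against the ratio of the library totals outside peaks (1.18), with Benjamini-Hochberg adjustment over 3273 peaks and a threshold of 0.05. The peaks had been selected on the same ChIP reads, so this test describes the list and is not independent evidence for it. With 1 library per group there is no replicate check, and every test compares these libraries, not conditions. Intervals are 95%, exact for shares and single folds and by a normal approximation on the log scale for the ratio of shares in peaks and for odds ratios, and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Folds over peaks used 1 read added to each count when summarised as a median.

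The summit of a peak was the point of highest density of ChIP read starts after moving each strand by 50% of the strand distance of 135 bp, in a triangular window of 100 bp on each side. Sequence around summits was recovered from the alignments: each placed read gives the assembly's bases, because the mismatch string records the assembly base at each mismatch. Uniquely placed reads of both libraries covered 85.0% of the bases within 100 bp of summits and 36.2% of those in flanks 500 to 1000 bp away. The design fixed before the data were examined assumed complete sequence. The test was kept, and unread bases were handled by pairing each read position within 100 bp of a summit with 1 read position 750 bp away, to the left where it was read and otherwise to the right. The share of peaks with a site was compared over these paired positions by an exact binomial test on discordant peaks, adjusted over the 23 motifs fixed beforehand. The result of 1 motif is not reported here, and control motifs that missed the threshold are named without values. These shares are lower than the true shares, since they cover only paired bases. A further measure, chosen after seeing the data, was the number of sites per kb of read sequence in centres and flanks, with an exact binomial test over sites and an interval from 2000 bootstrap samples of peaks. A site on either strand counted once. Joint occurrence of motifs was tested by Fisher's exact test in the 1576 peaks with at least 90% of the centre read, and motif density between score quartiles by 10000 permutations over peaks. CAGAC within 30 bp of AATMCACA sites was counted where at least 90% of the positions in that distance were read, and the same share over all such positions was added after seeing the data. All 8-base sequences with at least 20 sites were also compared between centres and flanks.

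The alternatives fixed beforehand were removal or retention of duplicates, reads without mismatch only, scaling by all uniquely placed reads, a window of 50 bp, random positions matched on GC content, CAGCTG or CAGATG in place of any E-box, distinct sequences in place of reads, and the 1637 peaks with a score of at least 70.51. Alternatives chosen after seeing the data were a ChIP to Input ratio set for each 2% bin of GC content, sequence that also used reads placed at several sites, sites per kb, and removal of scaffolds with a ChIP excess outside their peaks. Such scaffolds were defined by at least 20 reads outside peaks, a fold above 3 and an adjusted p below 0.05. A higher limit of 5 was tried after the list had been seen.

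The procedures were tested on simulated data. For the ChIP against Input test over 3273 peaks, 200 peaks were given a known fold over Input. The median estimate was 1.96 for a simulated fold of 2, 3.77 for 4, 7.60 for 8 and 16.5 for 16. The test called 6, 30, 70 and 92% of these, at an adjusted threshold stricter than in the real list, where most peaks passed, and 0.0976% of the 3073 peaks without a change. In random sequence with the unread positions of windows around the midpoints of 3273 peaks, 0 of 23 motifs were called. Bases were drawn alike for centres and flanks, so this cannot show calls that come from a difference in base composition between them. After AATACACA was placed in 1 of 4 centres, the 2 FOXH1 motifs were called, with a density ratio of 12.8 from both complete and read sequence. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.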

Results

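Smad2/3 chromatin from *Xenopus tropicalis* embryos at stage 10.5, when mesoderm and endoderm are being specified by Nodal signalling, was sequenced beside Input DNA, with 1 library per group and no replicates. The Smad2/3 library held 14938924 reads and the Input library 11247894. Of the Smad2/3 reads, 53.4% (exact 95% interval 53.3 to 53.4%) were placed uniquely on the xenTro2 assembly, against 56.8% (56.8 to 56.9%) of Input reads. Reads without any match made up 20.2% of the Smad2/3 library and 6.59% of Input. Reads listed at several places were 10.9 and 14.5%, and most of the remaining reads had too many places to be listed. The uniquely placed reads lay at 7473900 distinct positions for Smad2/3 and 6245685 for Input, with 6.25 and 2.31% duplicates. Their GC content was 38.9% in the Smad2/3 library and 42.2% in Input.

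The first comparison asked where Smad2/3 chromatin was recovered over Input. The deposited list held 3273 peaks on 773 scaffolds, with a median width of 635 bp (220 to 2715 bp), covering 2220960 bp in all. Smad2/3 reads were 5.11 times as frequent in these regions as Input reads (95% interval 5.03 to 5.20): 1.32% of uniquely placed Smad2/3 reads (1.31 to 1.32%) and 0.257% of Input reads (0.253 to 0.261%) started inside a peak. The median peak held 23 Smad2/3 and 4 Input reads at distinct positions, a median fold of 4.22 (quartiles 3.29 and 5.91). Around summits, forward-strand Smad2/3 reads piled up on the left and reverse-strand reads on the right, 135 bp apart, while Input reads showed no such pile-up. The summits were placed from the same Smad2/3 reads and this distance, so the shape and its contrast with Input follow in part from that choice.

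**Figure D1:**
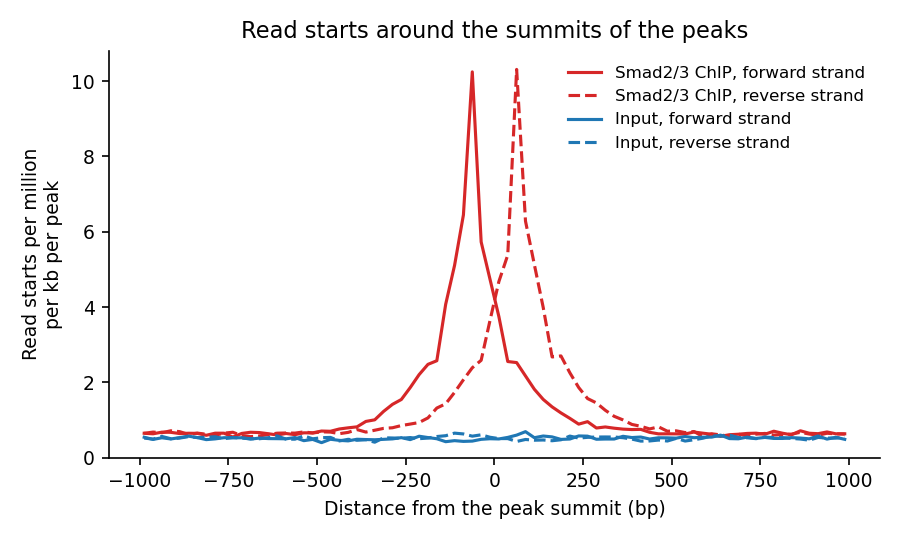
Read starts scaled to library size, per kb and per peak (vertical axis) against the distance from the peak summit in bp (horizontal axis), by strand, for the Smad2/3 ChIP and Input libraries over 3273 peaks. The Smad2/3 strands peak on either side of the summit, 135 bp apart, and the Input lines show no such rise, a contrast that follows in part from placing summits by the Smad2/3 reads.

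By the exact binomial test, 3148 of the 3273 peaks had more Smad2/3 than Input reads and 0 had fewer. With the ratio set for each GC bin, which was chosen after seeing the data, 2914 peaks had more. The peaks had been chosen on the same Smad2/3 reads, so an excess in most of them follows in part from that choice. The remaining 125 peaks had a median score of 54.17, against 71.84 for the called peaks. Scores are the authors' values. Peaks in the highest score quartile showed a fold of 6.08 (5.92 to 6.25), against 4.35 (4.18 to 4.53), 4.24 and 4.46 (4.31 to 4.61) in the quartiles from the lowest up. In 3 peaks no uniquely placed read was found in either library, and these lay on scaffolds 531, 62 and 83.

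**Figure D2:**
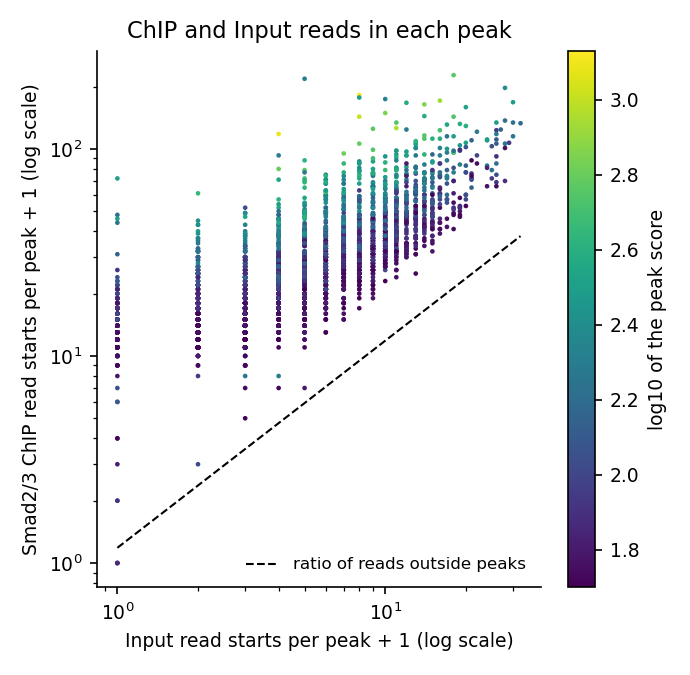
Smad2/3 ChIP against Input read starts at distinct positions in each of the 3273 peaks, plus 1, on log axes, coloured by log10 of the deposited peak score. The dashed line is the ratio of reads outside peaks, 1.18, and 3148 peaks passed the test for an excess of Smad2/3 reads.

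The peaks lay unevenly along the assembly. In 902 peaks (27.6%) another peak lay within 10 kb. Scaffold 1099 carried 38 peaks, between bases 7229 and 307668, and the next scaffold 34. On scaffold 1099 the Smad2/3 excess over Input also lay outside the peaks, at 6.68-fold (4.53 to 10.2, from 239 and 29 reads), and the scaffold's GC content was 56.4%. Both counts are low for a scaffold with reads up to base 313117. Windows of 500 bp outside peaks held on average 3.17 Smad2/3 and 2.68 Input reads. For uniquely placed reads outside peaks, the fold thus comes from sparse reads in both libraries, more so in Input, and not from a high unique Smad2/3 count. Placements of reads listed at several places on this scaffold, peaks included, numbered 11582 and 680. Relative to all such placements in each library this was a 17.8-fold Smad2/3 excess, so the unique counts leave out most placements on this scaffold.

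Among the 20 peaks with the highest scores, the first 2 lay side by side on the short scaffold 11144. The first, listed from -121 to 583, a start before the scaffold's first base, held 181 Smad2/3 and 7 Input reads, 21.8-fold (10.4 to 55.1). The other, at bases 788 to 1435, held 117 and 3 reads, 32.9-fold (11.0 to 162). The peak at scaffold 208, bases 1638404 to 1639644, followed with 142 and 7 reads, 17.1-fold (8.10 to 43.4). Scaffold 163, bases 1765545 to 1766401, held 79 and 3 reads, 22.2-fold (7.34 to 110.1). Scaffold 198, bases 1262038 to 1263174, held the most Smad2/3 reads of the 20, 226 against 17 in Input, 11.2-fold (6.86 to 19.6). All 20 passed the binomial test, the weakest being scaffold 444, bases 332724 to 333972, at 4.72-fold (2.80 to 8.44, adjusted p = 2.9e-10).

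The second comparison asked which sequence motifs marked the Smad2/3 peaks. SMAD CAGAC elements and FOXH1 sites were found in more peaks at the summit than 750 bp away. None of the 5 E-box motifs fixed beforehand passed the same test. FOXH1 is a forkhead factor that recruits activated SMAD2/3 to activin response elements. HEB and E2A, named with it in the series title, are basic helix-loop-helix factors that bind E-boxes. Of the 23 motifs fixed beforehand, 10 were found in more peaks at summits and 0 in fewer.

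The SMAD element CAGAC occurred at the summit of 27.1% of 3132 peaks over paired read positions, against 16.0% in flanks (657 peaks with a site only at the summit and 310 only in the flank, exact binomial adjusted p = 2.7e-28). Its density was 3.49 sites per kb at summits and 2.08 in flanks, a ratio of 1.68 (1.57 to 1.79). The palindromic element GTCTAGAC was rarer, at 0.416 and 0.0960% of 3125 peaks (exact binomial adjusted p = 0.0489). The GC-rich SMAD site GGCKCC occurred in 3.39 and 2.91% of peaks and did not pass the test (exact binomial adjusted p = 0.414), but passed it against random positions of matched GC content (2.22 against 1.36%, adjusted p = 0.0203).

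The FOXH1 site AATMCACA occurred at the summit of 7.10% of 3125 peaks against 2.18% in flanks (215 peaks only at the summit and 61 only in the flank, exact binomial adjusted p = 1.6e-20). Its density was 0.853 per kb against 0.215, a ratio of 3.97 (3.38 to 4.68). The relaxed site AATMMACA was found in 11.1 and 3.74% of peaks (exact binomial adjusted p = 1.0e-28). Of the 449 AATMCACA sites within 100 bp of summits, 329 had at least 90% of the positions within 30 bp read, and a CAGAC element lay within that distance of 91 of them (27.7%, exact interval 22.9 to 32.8%). The share was 21.4% for all summit positions read to the same extent. In flanks it was 4 of 43 sites (9.30%, 2.59 to 22.1%) and 13.6% of positions. The difference between sites and positions was not tested, and CAGAC and AATMCACA did not pass the test for joint occurrence in peaks (odds ratio 1.29, 0.986 to 1.69, Fisher's exact p = 0.0668, adjusted p = 0.242).

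Any E-box, CANNTG, occurred at the summit of 39.9% of 3130 peaks and in 39.2% of flanks (681 and 659 discordant peaks, exact binomial adjusted p = 0.651), with a density ratio of 1.03 (0.986 to 1.07). CAGCTG (3.67 against 3.55%, adjusted p = 0.876), CAGATG (5.78 against 6.17%, adjusted p = 0.651), CACCTG (4.47 against 5.46%, adjusted p = 0.128) and CACGTG (0.671 against 1.05%, adjusted p = 0.182) also missed the threshold by this exact test. The density of any E-box passed the threshold within 50 bp of summits (ratio 1.07, exact binomial adjusted p = 0.0281) and with sequence from reads placed at several sites (ratio 1.08, adjusted p = 0.00109). CAGATG went the other way, being less dense at summits than at random positions of matched GC content (ratio 0.859, 0.749 to 0.982, exact binomial adjusted p = 0.0367). In the higher-scoring peaks CACGTG was found in fewer peaks at summits (7 only at the summit and 20 only in the flank, exact binomial adjusted p = 0.0401).

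**Figure D3:**
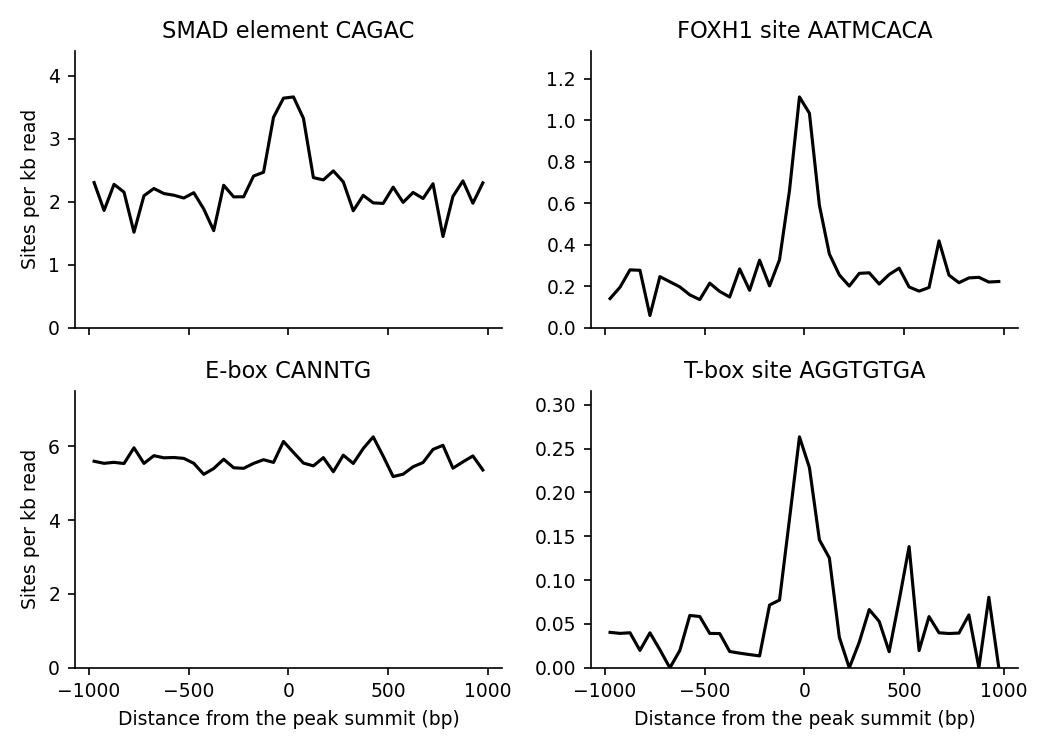
Sites per kb of read sequence (vertical axis) against the distance from the peak summit in bp (horizontal axis, bins of 50 bp) for the SMAD element CAGAC, the FOXH1 site AATMCACA, any E-box CANNTG and the T-box site AGGTGTGA over 3273 peaks. CAGAC, AATMCACA and AGGTGTGA rise at the summit (ratios to flanks 1.68, 3.97 and 4.94) and CANNTG changes little (1.03, and 1.07 within 50 bp).

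Sites of other gastrula factors were also found in more peaks at summits. The T-box site AGGTGTGA, bound by Eomes, VegT and Brachyury, was found in 1.60 against 0.288% of peaks (exact binomial adjusted p = 1.0e-07). The SOX site YYATTGTB was found in 14.8 against 6.40% (exact binomial adjusted p = 6.6e-27) and the POU site ATGYAAAT in 5.18 against 1.95% (adjusted p = 4.5e-12). The GATA site AGATAAG (2.27 against 1.63%, exact binomial adjusted p = 0.140) and the TCF/LEF site CTTTGATS (1.28 against 0.704%, adjusted p = 0.0628) missed the threshold, although both passed it as sites per kb (ratios 1.44 and 2.31) and with reads placed at several sites (adjusted p = 0.0459 and 0.00467). AGATAAG also passed within 50 bp of summits (exact binomial adjusted p = 0.0202) and CTTTGATS against positions of matched GC content (adjusted p = 0.0218).

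Of 7 control motifs, the sites of AP-1, CTCF, REST and C/EBP did not pass the test, and too few CTCF, REST and C/EBP sites were read to show a difference. Of the motifs made by reordering letters, GACAC (16.2 against 12.5% of peaks, exact binomial adjusted p = 5.5e-05) and ACMATACA (86 peaks only at the summit and 45 only in the flank, adjusted p = 0.00110) passed, and CGACTG did not. In the higher-scoring peaks the AP-1 site TGASTCA passed (18 peaks only at the summit and 6 only in the flank, exact binomial adjusted p = 0.0434), and with reads placed at several sites CGACTG was found in fewer peaks at summits (29 and 53, adjusted p = 0.0222). Without hits that overlapped a real site, the density ratio of GACAC fell from 1.38 to 1.21 and that of ACMATACA from 1.84 to 1.34. The differences between sites and their reordered controls were not tested.

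The third comparison asked whether E-boxes and FOXH1 sites occurred in the same peaks. In the 1576 peaks with at least 90% of the summit sequence read, 68.1% held an E-box, 16.5% an AATMCACA site, 51.6% a CAGAC element and 11.9% none of CAGAC, AATMMACA and CANNTG. Of these peaks, 1121 had a score of at least 70.51, so the shares lean to high-scoring peaks. They may not hold for the whole list, and no flank share stands beside them. E-box and AATMCACA occurred together in 182 of these peaks, 11.5% against 11.2% from the product of their shares (odds ratio 1.11, 0.833 to 1.49, Fisher's exact p = 0.512). With CAGCTG or CAGATG in place of any E-box, the joint share was 4.12% against 3.08% (odds ratio 1.58, 1.15 to 2.17, Fisher's exact p = 0.00523, adjusted p = 0.0419 over the 8 such tests). Overlapping E-box and AATMCACA sites were not removed from these counts.

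CAGAC and AATMCACA sites were densest in the peaks with the highest scores. AATMCACA rose from 0.378 sites per kb (0.275 to 0.507) in the lowest score quartile to 1.39 (1.21 to 1.59) in the highest, a ratio of 3.68, and CAGAC from 2.76 (2.48 to 3.08) to 4.68 (4.34 to 5.04), a ratio of 1.69. For both the permutation p was 1e-04, the smallest that the permutations can give (adjusted p = 0.000317). The GC-rich SMAD site GGCKCC (ratio 1.22, permutation p = 0.346), the T-box site AGGTGTGA (permutation p = 0.145) and CAGCTG (ratio 0.995, permutation p = 0.974) did not pass the same test. CANNTG (ratio 1.11, permutation p = 0.0318, adjusted p = 0.0671) and CACGTG (ratio 0.338, permutation p = 0.0368, adjusted p = 0.0699) missed the threshold after adjustment. The SOX site YYATTGTB (ratio 1.58, permutation p = 1e-04) and the POU site ATGYAAAT (ratio 1.91, permutation p = 0.0002) passed it. The reordered controls also rose with the score, ACMATACA by 3.70 and GACAC by 1.48 (permutation p = 1e-04 for each). Without sites that overlap a real one they rose by 2.23 (permutation p = 0.0042) and 1.34 (permutation p = 0.0025).

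**Figure D4:**
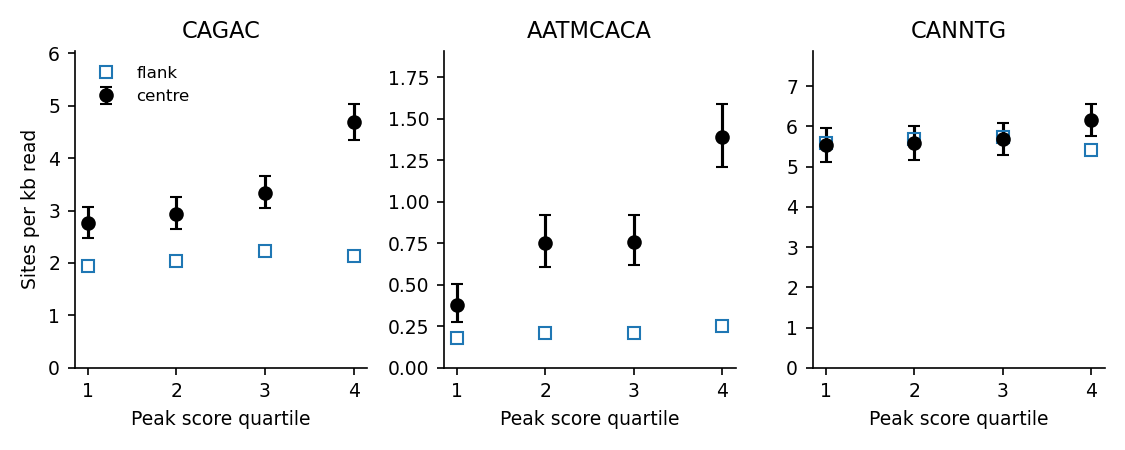
Sites per kb of read sequence (vertical axis) by quartile of the deposited peak score, from lowest (1) to highest (4), for CAGAC, AATMCACA and CANNTG. Filled circles are summit centres with exact 95% counting intervals and open squares are flanks, and AATMCACA in centres goes from 0.378 to 1.39.

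Of the 20 peaks with the highest scores, 15 held CAGAC within 100 bp of the summit, 10 held AATMMACA, 9 held both and 16 held an E-box. On scaffold 12, the peak at bases 4633370 to 4634776 (170 and 15 reads, 9.57-fold, 5.64 to 17.5) had AATACACA at bases 4634347 to 4634354, 77 bp right of the summit. Its surroundings at bases 4634331 to 4634370 read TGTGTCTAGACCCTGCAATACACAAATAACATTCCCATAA. On scaffold 782, the peak at bases 348510 to 350066 (142 and 17 reads, 7.05-fold, 4.25 to 12.4) had AATCCACA at bases 348995 to 349002 within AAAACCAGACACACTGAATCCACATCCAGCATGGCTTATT, bases 348979 to 349018. On scaffold 432, the peak at bases 242193 to 243163 (105 and 7 reads, 12.7-fold, 5.94 to 32.3) had AATACACA at bases 242652 to 242659 within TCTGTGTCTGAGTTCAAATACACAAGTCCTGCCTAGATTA, bases 242636 to 242675, and was the only 1 of the 20 with AGGTGTGA. Neither of the 2 peaks on scaffold 11144 held an AATMMACA site, nor did others of the 20, and the summit sequence of all 20 was read completely.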

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

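The tests of GC content, of uniquely placed sequence, of adapter sequence and of GC content on whole scaffolds, the comparisons at matched GC content, the ratio set for each GC bin, the reads with changed bases and the count of each sequence once were chosen only after the results they bear on were seen. The other tests below were set out beforehand.

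Reads without a match made up 20.2% of the Smad2/3 library against 6.59% of Input, and no comparison used them. Adapter sequence as the main source is argued against by its start in 0.980% of them. Embryo DNA missing from the assembly and present alike in Input is argued against as the main source by these shares, since it could not exceed the 6.59% of Input. The search of pieces could therefore not have come out otherwise on this point. In it, 20-base pieces of these reads were found among unmatched Input reads at 18.6% of the rate of held-out Input reads (with each sequence once, 3.16 against 17.7%). Part of the unmatched Smad2/3 reads may come from such DNA. Sequencing errors in reads from the assembled genome remain open, because the pieces were found in Input-recovered sequence at 6.62% of the rate of uniquely placed Smad2/3 reads, but changing 3 bases at random in the latter already lowered their share from 24.6 to 2.83%. DNA of another source also remains open and was not tested, and no biological explanation was tested.

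Scaffolds with a Smad2/3 excess also outside their peaks numbered 47 of the 6186 tested, of which 8 carried 56 peaks (1.71% of the list), while 289 scaffolds had an Input excess over the same limit. Raising the limit from 3-fold to 5-fold left 14 scaffolds and the same 8 with 56 peaks. GC bias between the libraries runs the other way for scaffold 1099, which has the most peaks: windows of its GC content had 0.446 times the usual Smad2/3 to Input ratio. The 56 peaks held 0 AATMMACA sites where 9.17 would follow from other peaks of the same GC content, with an upper limit of 0.592 sites per kb against 1.47 (without matching the upper limit was 0.583, also below the other peaks), as DNA other than Smad2/3-bound chromatin in the library could give. CAGAC was also rarer there, with 7 sites where 32.3 would follow from the same GC content (upper limit 2.21 sites per kb against 4.95). Scaffold 1099 alone carried 38 of the 56 peaks, so these site counts rest largely on 1 scaffold. Smad2/3 had 1649 uniquely placed reads on it and Input 94. Binding through neither site was not tested as a biological explanation, and by itself it would leave the sparse Input reads unexplained.

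The SMAD elements CAGAC and GTCTAGAC, the FOXH1 sites and the T-box site were denser at summits than in flanks. The SMAD site GGCKCC did not pass (density ratio 1.17, 0.988 to 1.38, exact binomial adjusted p = 0.135). GC content is argued against by the AATMCACA ratio of 5.07 against random positions of matched GC content. The gain at matched GC content was not particular to the site, since the reordered control ACMATACA also passed there. It was found in 78 peaks only at the summit and in 19 only at the random position (exact binomial adjusted p = 3.7e-09). For AATMCACA these numbers were 176 and 30. Control hits that overlap a real site were not removed from these numbers. Restriction to uniquely placed reads is argued against by a ratio of 4.28 when reads placed at several sites were added. Adding them raised the AATMCACA flank positions read only from 1005264 to 1266972. Gaps that neither kind of read covered stayed unread, so the test cannot speak to them. Letter composition is argued against by the rank of the FOXH1 orders: AATACACA stood 1st of 168 orders of its letters and AATCCACA 2nd of 280, within the top 0.714%. Recruitment through FOXH1 and SMAD sites may account for the pattern, as a hypothesis from 1 library in which the reordered controls also rose.

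Reads matched to the contaminant sequence set were 0.481% of the Smad2/3 library and 0.0890% of Input, a signal outside every comparison, and 0.00858 and 0.00246% with each distinct sequence counted once. Placements of reads listed at several sites fell inside peaks for 0.301% in the Smad2/3 library and 0.0440% in Input. Away from peaks, 25 windows of 500 bp had more Smad2/3 than Input reads, and 55 did with the ratio set for each GC bin.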

How the results depend on the processing

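The sites-per-kb measure, the added reads placed at several sites, the ratio set by GC content and the removal of scaffolds with an excess were chosen after seeing the data. Of 67 alternative values, 45 were counted as kept and 0 as reversed. Motif tests were kept by direction and side of the threshold, read shares by their interval, and peak numbers by closeness to the main count. Score-quartile ratios were counted as kept without a check, and only motif tests could be counted as reversed. CAGAC and AATMCACA stayed past the threshold under all 11 alternatives of each. Peaks with a site only at the summit outnumbered those with it only in the flank by 1.86 to 2.51 for CAGAC and 3.52 to 6.68 for AATMCACA, and the sites-per-kb ratios were 1.68 to 1.86 and 3.97 to 5.07. CANNTG passed it in 2 of 11, as sites per kb within 50 bp (1.07) and with reads placed at several sites (1.08). The E-box and FOXH1 odds ratio passed it with CAGCTG or CAGATG (1.58) and not under the others (1.07 to 1.32). The number of peaks with an excess was 1623 of the 1637 with a score of at least 70.51, which follows from testing fewer peaks, and 2914 to 3156 under the other settings. The share of reads in peaks moved to 1.28% of Smad2/3 reads (ratio 4.93) without duplicates, to 0.897 and 0.161% (ratio 5.59) in those 1637 peaks, to 0.262% of Input reads without mismatches, and to 1.28% (ratio 5.02) without the scaffolds with an excess. As distinct sequences, the Smad2/3 library had 58.7% unique, 22.0% unmatched, 11.5% at several places, 7.79% at many and 0.00858% in the contaminant set. Input had 66.1, 6.50, 15.8, 11.4 and 0.00246%. Apart from the smaller number of peaks, the cause of these shifts was not tested. No paired analysis was possible because each group has 1 library. Alternatives for distances to transcription starts and for gene lists, including reads around listed genes, were not run. Depth limits single peaks: the simulated test called 30% of 4-fold changes where 200 of 3273 peaks changed, with a stricter adjusted threshold than in the real list, where most peaks passed.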

Other observations

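The hypotheses below were tested on the same library in which the patterns were seen. The tests on peak score and on reordered controls without overlap, and the scans of 8-base sequences and of single E-boxes, were chosen after the results were seen, as were the sites named from them. The test of CAGCTG or CAGATG with FOXH1 sites was fixed beforehand as an alternative, and was taken up as a hypothesis after its value was seen.

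A scan of sequences beyond the fixed motifs found more that marked the summits. Of 20530 sequences of 8 bases, 942 were denser at summits and 557 in flanks (exact binomial test, Benjamini-Hochberg adjusted). AATACACA, a form of the fixed FOXH1 site, had a ratio of 4.19 (3.45 to 5.16), and with a C before it, CAATACACA, 8.91 (6.16 to 14.1). AACAATGG, which matches the fixed SOX site on the other strand, had 4.31 (3.27 to 5.97). TAATTAGC, which holds the homeobox core TAATTA and is outside the fixed motifs, had 5.31 (3.96 to 7.42). TATATATA was rarer at summits, at 0.195 of its flank density (0.114 to 0.304). Of the 359 tested sequences that hold an E-box, CANNTG, 10 were denser at summits and 3 in flanks. The 25 with CAGCTG and the 46 with CAGATG included 0 in either direction, and these counts were not tested against those of other sequences.

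Single E-boxes went both ways in a further scan of all 10. CAAATG (1.25, 1.14 to 1.37, exact binomial adjusted p = 1.5e-05) and CAATTG (1.45, 1.21 to 1.73, adjusted p = 0.000382) were denser at summits and CAACTG (0.781, 0.679 to 0.895, adjusted p = 0.00126) in flanks, and the other 7 missed the threshold.

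A hypothesis is that E-boxes go with FOXH1 sites in these peaks. Peaks with an AATMCACA site held CAGCTG or CAGATG more often, with an odds ratio of 1.58. That value was seen before the hypothesis was taken up, so it cannot test it. Overlapping sites were not removed, so 1 stretch of sequence can count as both. Any E-box gave 1.11 (Fisher's exact p = 0.512), and neither CAGCTG nor CAGATG passed the test at summits.

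A further hypothesis is that Smad2/3 recovery goes with FOXH1 sites. AATMCACA density rose 3.68-fold from the lowest to the highest score quartile. The fold over Input did not follow it throughout: from the lowest quartile up, density was 0.378, 0.752, 0.757 and 1.39 sites per kb and the fold 4.35, 4.24, 4.46 and 6.08. The reordered control ACMATACA rose 3.70-fold with all its sites and 2.23-fold without those that overlap a FOXH1 site, so a general shift in sequence could not be excluded, and the difference between site and control was not tested.

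A homeobox contribution to the summits beyond AT content was also asked. TAATTA had the highest ratio of the 14 orders of its letters, 2.68, but with 14 orders the best possible rank is the top 7.14%, so the test could not reach the 5% set for it.

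Away from peaks, 126 windows of 500 bp had more Input than Smad2/3 reads, with a median GC content of 62.2%. With the ratio set for each GC bin 8 were left (6.35%), and the median Smad2/3 count in the 126 was 0.946 times the mean of windows outside peaks.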
